A study of Mus musculus with 2 samples.

How the data were processed

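Polyadenylated RNA was sequenced from the heart of mouse embryos of strain B6NCrl at embryonic day 14.5, per the labels. The labels give 2 biological replicates, with 1 library each, and these form the single group analysed here. The same labels describe each heart as coming from 1 animal and the sex as a mixture of male and female, so whether an RNA sample came from 1 embryo or from several was left open.

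The deposited files hold 1 gene table and 1 transcript table per library. Their column names are those written by the program RSEM, per the file headers, and the accompanying text states the assembly mm10 and the gene annotation release M4. The aligner, the program versions, the strand setting and any read filter are not given in the sources used here. The expected count, an estimate that divides reads matching several transcripts among them, is not scaled for depth and was deposited by the authors for every gene and transcript. TPM, the expected count divided by effective length and scaled to the same total in each library over all rows, was likewise deposited by the authors, and that sum includes the rows for the phiX174 sequencing control. FPKM, scaled by length and library size, was also deposited and served only in an alternative. The percent of a gene's TPM assigned to each transcript was read as deposited. Posterior-mean TPM and counts were deposited beside these and add a prior to every transcript, so that genes without a read had a median of 2.19 posterior-mean TPM in replicate 1. Effective length was length minus 35 bases in all files.

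Each table held 43346 mouse genes, 96 spike-in rows, 1 phiX174 row and 26248 short numbered rows that carry no gene name. Gene identifiers were matched without their version to GENCODE release M21 of the same assembly for symbols, positions and gene classes, and 42462 matched. The remaining 884 have no symbol here. The annotation release used by the authors was not used here. Control, spike-in and numbered rows stayed out of the gene read totals and of every test.

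The choices of tests, gene lists, pairs and alternatives were made before the data were examined, except those named in the closing parts as made afterwards and the comparison of 36-base windows of transcripts (GENCODE release M21) between the globin genes, also made afterwards. Most genes named in the text were fixed by rule. They are the 15 nuclear protein-coding genes of highest mean TPM, up to 5 members of each list with the highest mean TPM together with members under 1 TPM in both libraries, every gene of the pairs, the 10 genes with the largest ratio in each direction among genes with a mean of at least 5 TPM, the genes with isoforms of interest, and all members of the sex chromosome list. Outside this rule, and chosen after their values were seen, are the list members Mybpc3, Actn2, Obscn, Scn5a, Irx4, Nkx2-5, Tek, Mki67, Gapdh, Plagl1 and mt-Co2, the gene Rn7sk, ENSMUSG00000045999, and the ribosomal protein genes and chromosome 1 pseudogenes of the closing part other than Gm28437 and Gm29216. The 31 lists cover sarcomere, calcium handling, ion channels and gap junctions, cardiac transcription factors, atrial and ventricular cardiomyocytes, the conduction system, endothelium and endocardium, lymphatic endothelium, epicardium, valve and cushion mesenchyme, fibroblast and matrix, smooth muscle and pericyte, neural crest with glia and neurons, erythroid cells, macrophages and leukocytes, megakaryocytes and platelets, lung epithelium, liver, thymus, skeletal muscle, proliferation, cell cycle inhibitors, glycolysis, fatty acid oxidation, mitochondrially encoded genes, immediate early and heat shock genes, hypoxia, imprinted genes, signalling and sex chromosome genes. They were drawn up from textbook knowledge.

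A gene was called detected at a TPM of at least 1 in both libraries. Whether both libraries could be 1 library given again was tested by a chi-square test of the counts over genes with a mean of at least 10 reads. Correlations were taken across genes on log2(TPM + 1), and genes are not independent replicates. The spread between replicates was estimated with edgeR 4.0.16 as the common biological coefficient of variation, on expected counts rounded to whole numbers, with TMM normalization and nuclear genes of at least 10 reads on average. Ratios between replicates used log2(TPM + 0.1). For named genes the ratio of the shares of gene reads is given with an exact binomial 95% interval. Intervals and floors cover counting error only, because reads without molecular identifiers are not independent molecules. Where a gene had 0 reads in a library, its ratio was bounded with a floor of 3 reads. The 34 gene pairs were compared with limma 3.58.1, using its treat test against a 2-fold difference with Benjamini-Hochberg adjustment at 0.05 over the pairs alone. Whether a list moved between libraries was judged by the percentile of its median log2 ratio among 10000 random lists of the same size, matched on mean TPM in 10 bins, for lists with at least 5 members. No test of a condition exists in this design, and an exact permutation test on 2 libraries cannot give a p below 0.5.

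The steps were tested on simulated data. On 393 simulated genes a coefficient of variation of 0.3, 0.6, 1 and 1.5 came back as 0.321, 0.615, 0.932 and 1.446. In 34 simulated pairs, 5 of 17 with a 16-fold difference and 0 of 17 unchanged pairs were called. A list raised 8-fold stood at the 100.0 percentile, and 2 of 14 unchanged lists fell outside the 95% range. Alternatives were DESeq2 1.42.0 size factors, other detection limits, pseudocounts and filters, posterior-mean values, TPM rescaled over nuclear protein-coding genes, shares of expected counts, and each library on its own. Added after the data were seen were detection at 3 reads, correlation over all genes of the files, shares over mouse genes alone and a count of ratios among genes with at least 10 reads on average. Calculations ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 and in R 4.3.3.

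The tables summed to 294932 reads in replicate 1 and 293232 in replicate 2, of which 33694 and 34276 fell on mouse genes. At that depth a single read was worth 5.41 and 5.36 TPM for the median gene above 0, so the detection limit of 1 TPM asks for little more than a read. Only 23 and 16 genes lay above 0 and under 1 TPM.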

Results

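The data are a profile of polyadenylated RNA in the mouse heart at embryonic day 14.5, when the chambers are septating and the ventricular wall is thickening. The single group held 2 biological replicates, and no other tissue, age or genotype was compared. Reads on mouse genes numbered 33694 in replicate 1 and 34276 in replicate 2, spread over 7218 and 6542 genes above 0. They were 11.4% (95% Wilson interval 11.3 to 11.5) and 11.7% (11.6 to 11.8) of all reads in the tables, and the row of the phiX174 sequencing control held 88.6% (88.4 to 88.7) and 88.3% (88.1 to 88.4). Because TPM was scaled with that control included, the levels after the first ranking are mainly given as reads. The error shown is the SD of n = 2 libraries unless stated.

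The first question was which genes the embryonic heart libraries held at the highest level. Among nuclear protein-coding genes the highest mean TPM belonged to Eef1a1, a translation elongation factor (2825 ± 402 TPM), and to Myh7, the slow myosin heavy chain of the fetal ventricle (2160 ± 2310). Actc1, cardiac alpha-actin (1890 ± 1944), Tpt1 (1593 ± 1552), Lars2, the mitochondrial leucyl-tRNA synthetase (1402 ± 1110), Igf2 (1341 ± 957), Tuba1b (1314 ± 1595) and Tnnt2, cardiac troponin T (1118 ± 1254), came next. Below them stood Rps17 (997 ± 1350), the myosin light chains Myl2 (878 ± 1020), Myl7 (876 ± 1107) and Myl3 (744 ± 249), Cox7c (843 ± 1193), Rpl24 (810 ± 771) and Rps29 (743 ± 1051). Some of these levels rested almost wholly on 1 library: in replicates 1 and 2, Cox7c had 38 and 0 reads, Rps29 0 and 43 and Rps17 47 and 1.02. By reads, Ttn, the giant sarcomere spring at chromosome 2, 76703980 to 76982547 (mm10), held 454 and 401 in replicates 1 and 2. The SD exceeded the mean for 9 of these 15 genes, so their order was not resolved by n = 2.

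The second question was how far the replicates gave the same levels, and most genes with a mean of at least 10 reads differed over 2-fold. Ttn (ratio of replicate 2 to replicate 1 of 0.868, exact 95% interval 0.757 to 0.995), the calcium pump gene Atp2a2 (53 and 46 reads, 0.853, 0.562 to 1.29) and the proteoglycan gene Vcan (28 and 28 reads, 0.983, 0.561 to 1.72) were close in reads. In TPM, where the length given for a gene enters, Atp2a2 stayed close (159 and 139), but Vcan had 45.9 and 178 and Ttn 300 and 125. Tnni1, slow skeletal troponin I, had 82 and 3 reads, a ratio of replicate 1 to replicate 2 of 27.8 (9.19 to 138), and Myl7, the atrial regulatory light chain, had 4 and 75 reads, a ratio of 18.4 (6.91 to 69.4) the other way. Cpne9 had 196 reads in replicate 1 and 0 in replicate 2, at least 66.5-fold higher, while mt-Co3 had 0 and 1411 and its near copy Gm28437 had 423 and 0, so no ratio is given for mt-Co3. Protein-coding nuclear genes took 69.8% and 67.9% of gene reads, mitochondrial genes 9.04% and 13.7%, and pseudogenes 8.85% and 10.6%.

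**Figure D1:**
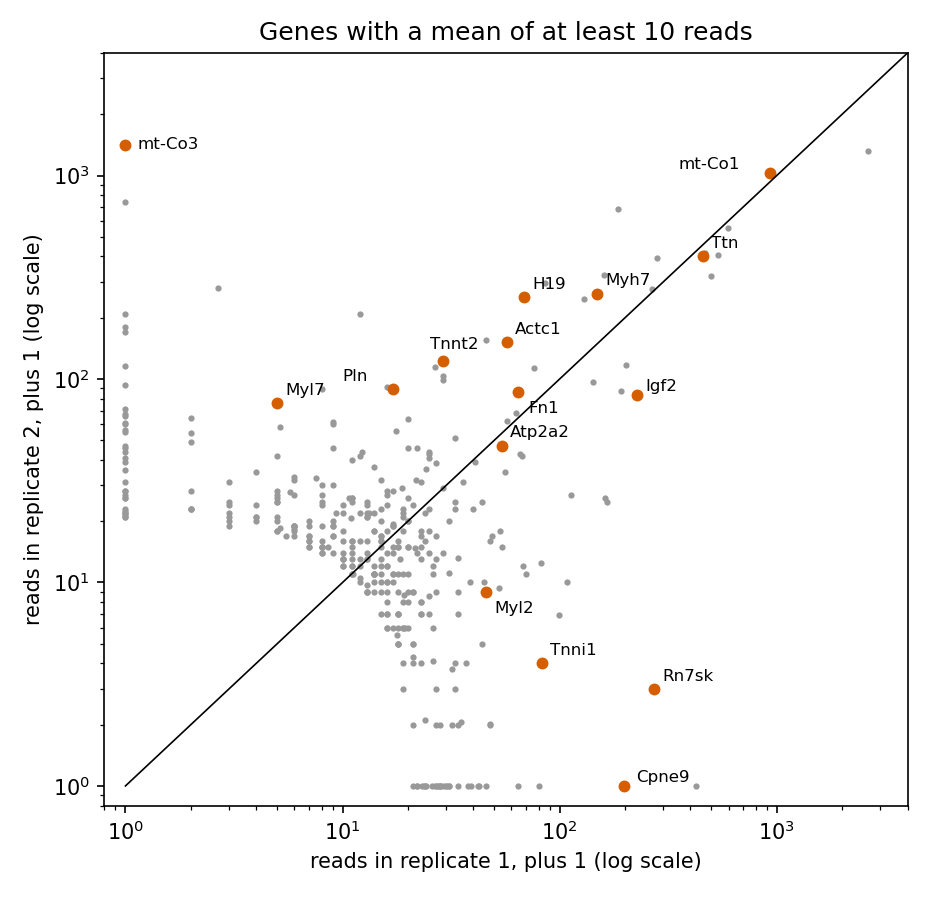
Reads per gene in replicate 1 (horizontal) against replicate 2 (vertical) for the 401 genes with a mean of at least 10 reads, both plus 1 on log scales, with the line of equal reads and named genes in orange. Ttn (454 and 401 reads) lies near the line, while Tnni1 (82 and 3) and Myl7 (4 and 75) lie far from it on opposite sides, and the lower left corner is empty because of the limit on the mean.

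A chi-square test of the counts over 401 genes gave 10773 on 400 degrees of freedom, 26.9 per degree, so the libraries were not 1 library given again. This test compares these libraries and not conditions. Across the 9696 genes above 0 in either library, Pearson's r of log2(TPM + 1) was −0.04 and Spearman's rho −0.08. A choice of genes by their presence in either library pulls these values down by construction. Over genes of at least 1 TPM in both libraries, a choice by joint presence, r was 0.577. Over all 43346 genes, a choice made after seeing the data, it was 0.515, raised by the genes at 0 in both libraries. Across the 401 genes with a mean of at least 10 reads, r of log2(reads + 1) was −0.084 and rho of the reads −0.27. The limit on the mean can pull these values down as well. The biological coefficient of variation from edgeR was 1.12 (bootstrap interval over genes 1.03 to 1.22) for 393 nuclear genes, and 0.930 for protein-coding genes alone.

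In all, 4056 genes were detected in both libraries and 9672 in either, and 1101 had at least 3 reads in both. Of the 6235 genes with a mean of at least 5 TPM, 4777 (76.6%) differed over 2-fold between replicates, 2613 higher in replicate 1 and 2164 in replicate 2. A single read was worth 5.41 and 5.36 TPM for the median gene above 0, so that limit admits genes with very few reads. Counting error alone can take such genes over 2-fold, and its share of the 76.6% was not estimated. Among the 401 genes with a mean of at least 10 reads, 244 (60.8%) did so by share of gene reads, and for 246 the exact interval of the ratio excluded 1. At 0 in a single library were 62 of these genes, where counting error alone would give 0.0001. The 10 largest ratios towards replicate 1 comprised 7 pseudogenes, the protein-coding genes Cox7c (38 and 0 reads) and Cpne9, and ENSMUSG00000095468, which has no symbol here (37 and 0 reads). Towards replicate 2 they comprised 5 pseudogenes, mt-Co3, the mitochondrial tRNA genes mt-Te (0 and 20 reads) and mt-Tg (0 and 3), Rps29 (0 and 43) and the microRNA gene Gm22133 (0 and 6.45). All 20 had 0 reads in 1 library, so their order follows the pseudocount and gene length, and with a floor of 3 reads mt-Tg was not resolved as higher (0.983). Outside the rule for named genes and chosen after its values were seen, the small nuclear RNA gene Rn7sk had 272 and 2 reads.

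The next question was which cardiac and other cell programmes were represented. Of 28 sarcomere genes, 25 were detected in both libraries, and together they held 1151 and 1465 reads, 3.84 ± 0.61% of gene reads and 1.13 ± 0.08% of TPM. Besides Ttn and Myh7 (147 and 261 reads), the thick filament gene Mybpc3 (28 and 98), the giant M-band protein gene Obscn (15 and 13), the Z-disc gene Actn2 (39.9 and 38), and the light chains Myl3 (65 and 42) and Myl4 (24 and 43) were read in both. Myom2, an M-band gene of mature muscle, had 0 reads in both, which allows up to 3 reads per library. Myh7 had more reads in replicate 2 but 3793 TPM in replicate 1 against 526 in replicate 2, because its reads were assigned to transcripts with a mean length of 533 bases in the first and 6128 in the second.

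**Figure D2:**
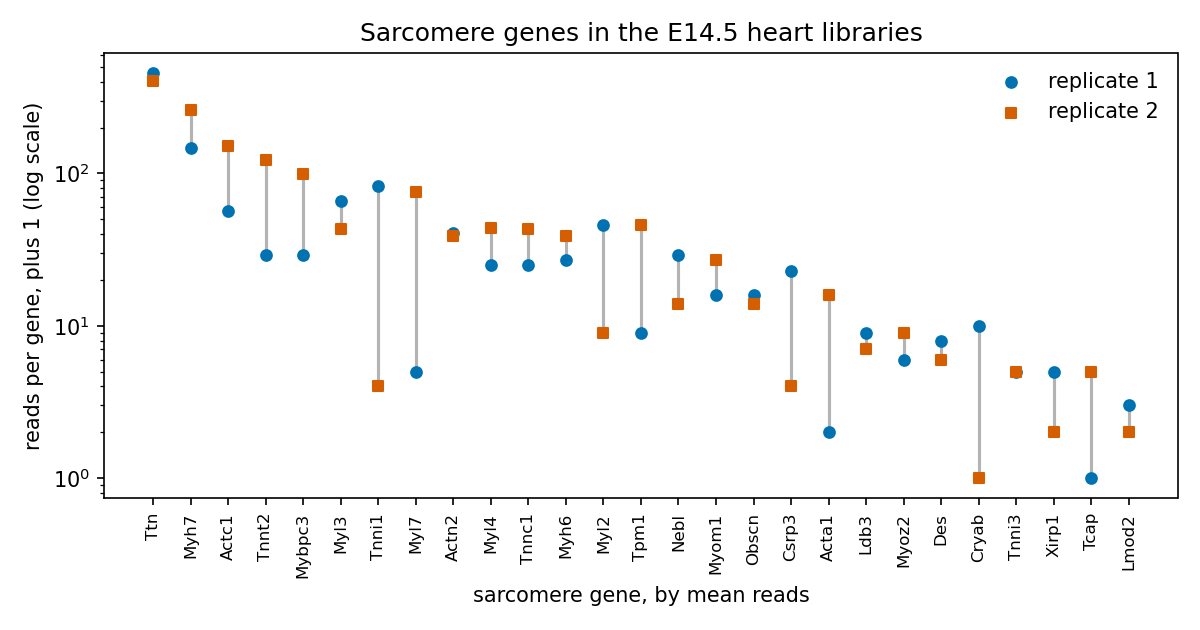
Reads per gene, plus 1 on a log scale, for the 27 sarcomere genes with a read in either library, ordered by mean, with replicate 1 as circles, replicate 2 as squares and a line joining both. Ttn (454 and 401) and Actn2 (39.9 and 38) nearly coincide, while Tnni1 (82 and 3), Myl7 (4 and 75) and Myl2 (45 and 8) are far apart.

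Calcium handling genes were detected for 10 of 14, with 145 and 195 reads. Pln, the phospholamban gene that restrains the calcium pump (16 and 88 reads), Atp2a2, the storage protein gene Casq2 (14 and 12), the exchanger gene Slc8a1 (26 and 8) and the release channel gene Ryr2 (16 and 18) led the list, and Sln and Fkbp1b had no read. Ion channel and gap junction genes were detected for 7 of 21, led by the connexin gene Gja1 (33 and 8). The sodium channel gene Scn5a had 1 and 4 reads, and Hcn4, Kcnj2 and 6 others had none in either library. Cardiac transcription factors were detected for 13 of 24, among them Tead1 (6 and 13), Gata4 (3 and 7), Tbx20 (16 and 10) and Mef2a (17 and 6). Nkx2-5, an early cardiac factor, had 0 and 4 reads, and Isl1, Hand1 and Tbx2 had 0 in both, which at this depth is no sign of absence.

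Genes on the lists of both chambers were read, but not all of their members. The atrial members Sln, Mybphl, Stard10 and Bmp10 and the ventricular members Hand1 and Mycn had 0 reads in both libraries. Atrial genes were detected for 4 of 12 with 32 and 135 reads, most of them from Myl7 and Myl4, which also stand in the sarcomere list, while Nppa, the atrial natriuretic peptide gene, had 0 and 7 reads. Ventricular genes were detected for 6 of 10 with 138 and 150 reads, mostly from Myl3, Pln and Myl2 (45 and 8), and the ventricular factor Irx4 had 3 and 4. Conduction system genes were detected for 4 of 13 (22 and 17 reads), with Cacna2d2 at 12 and 1 and Id2 at 2 and 7, and none had 3 reads in both libraries.

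Genes on the lists of other cells of the heart were read as well. Fibroblast and matrix genes were detected for 10 of 14 (176 and 192 reads, 0.541 ± 0.027% of gene reads), with fibronectin gene Fn1 (63 and 85), Sparc (55 and 34), and the collagen genes Col1a2 (12 and 24) and Col3a1 (13 and 10). Valve and cushion genes were detected for 3 of 12, where Vcan had 28 reads in each library and the matricellular gene Postn 20 and 1. Endothelial and endocardial genes were detected for 7 of 19 (53 and 44 reads), including Eng (18 and 2), Cdh5 (5 and 13) and Tek (11 and 6), and lymphatic genes for 2 of 5, led by Prox1 (5 and 4). Epicardial genes were detected for 3 of 11 with 12 and 7 reads, Upk3b having 3 and 1. Smooth muscle and pericyte genes were detected for 4 of 11, with smooth muscle actin gene Acta2 at 5 and 32 and Cnn1 at 7 and 3. Mylk, Rgs5 and Kcnj8 of that list, and Ccl21a and Reln of the lymphatic list, had 0 reads in both libraries. Neural crest, glial and neuronal genes were detected for 1 of 13, Stmn2, with 1 read in each library.

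Blood genes came mainly from red cells. Erythroid genes were detected for 5 of 14 (121 and 63 reads), with the embryonic beta-like globin gene Hbb-y at 43 and 24 and the adult globin genes Hbb-bt at 31.8 and 21.9 and Hbb-bs at 34.2 and 1.06. Hbb-bt shares 59.1% of its 36-base windows with Hbb-bs, so the division between these is uncertain, while Hbb-y shares 0% with either. Macrophage and leukocyte genes were detected for 3 of 12 with 3 and 5 reads, Csf1r having 1 in each, and the 6 megakaryocyte and platelet genes had no read. Markers of neighbouring organs were near 0: the 6 thymus genes had no read, lung epithelium 0 and 1 (Sftpb), skeletal muscle 1.05 and 0 (Actn3), and liver 2 and 2 (Afp). Counting error allows up to 3 reads, 0.00102% of all reads, where 0 was observed.

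**Figure D3:**
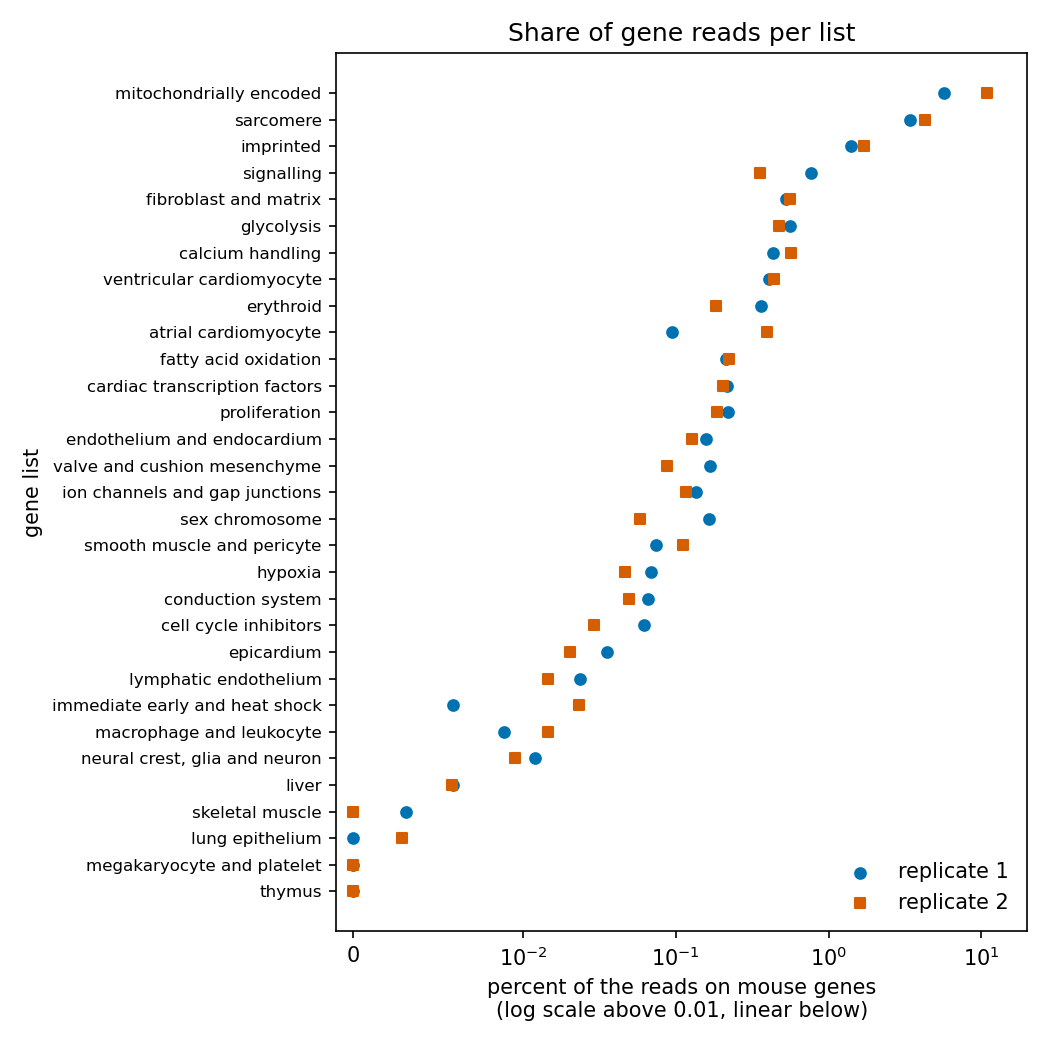
Percent of the reads on mouse genes held by each of the 31 gene lists (rows, ordered by the mean), replicate 1 as circles and replicate 2 as squares, on an axis that is logarithmic above 0.01 and linear below. Mitochondrially encoded (5.70 and 10.8%), sarcomere (3.42 and 4.27%) and imprinted genes (1.39 and 1.70%) led in both libraries, and thymus and platelet genes lay at 0.

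Mitochondrially encoded protein genes held 1920 and 3708 reads (8.26 ± 3.62% of gene reads), with mt-Co1 at 927 and 1030, mt-Nd4 at 267 and 277, mt-Cytb at 498 and 320 and mt-Nd1 at 85 and 295, yet 7 of 13 were detected and mt-Atp6, mt-Nd3 and mt-Nd4l had 0 in both. Near-identical copies of several of these genes lie on chromosome 1, and the division of reads between copies is uncertain. Glycolytic genes were detected for 15 of 18 (188 and 163 reads), among them Tpi1 (43 and 4), Ldha (19 and 19), Ldhb (31 and 2.75) and Pkm (10 and 24), while Gapdh had 1 and 3. Fatty acid oxidation genes were detected for 10 of 19 (72 and 76 reads), with Hadhb at 17 and 10, Hadha at 4 and 24, Cpt1b at 18 and 3 and the fatty acid binding protein gene Fabp3 at 0 and 18.

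Imprinted genes were detected for 11 of 12 and held 468 and 584 reads, 1.55 ± 0.22% of gene reads, led by the long noncoding RNA H19 (67.7 and 252 reads) and the fetal growth factor gene Igf2 (226 and 82), with Igf2r (75 and 112), Grb10 (35 and 30), Mest (16.6 and 54.7) and Plagl1 (11 and 21). Signalling genes were detected for 9 of 28 (259 and 121 reads), and Igf2 provided most of their reads, followed by Cxcl12 (2 and 9). Proliferation genes were detected for 15 of 21 (74 and 64.1 reads), including Mki67 (9 and 17), Top2a (15 and 5), Pcna (11 and 1) and Cdk1 (6 and 4). Cell cycle inhibitors were detected for 3 of 8, led by the imprinted gene Cdkn1c (11 and 7). Hypoxia genes were detected for 2 of 8, with Pdk1 at 6 and 11 and Bnip3 at 9 and 0, and immediate early and heat shock genes for 0 of 12, Jun having 0 and 4 reads. Of the sex chromosome genes, Xist, the RNA of the inactive X chromosome, had 53.2 and 14 reads and the Y-linked gene Ddx3y 2 and 3, Kdm5d had 0 and 3, and Eif2s3y and Uty had none. Over all lists, 169 of 387 members were detected in both libraries, 96 in a single library and 122 had 0 in both.

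Pairs of related genes asked which paralogue or isoform partner prevailed in the embryonic heart. In 3 pairs the cardiac form was read and the skeletal partner was at 0: Tnnc1 had 66 reads over both libraries against 0 for Tnnc2, at least 22-fold higher, Atp2a2 99 against 0 for Atp2a1, at least 33-fold, and Ryr2 34 against 0 for Ryr1, at least 11.3-fold, each with a floor of 3 reads over the group. Other skeletal partners were read in replicate 2, Casq1 (0 and 6 reads) beside Casq2 (14 and 12) and Tnnt1 (0 and 11) beside Tnnt2 (28 and 121). Pln had 104 reads (16 in replicate 1 and 88 in replicate 2) against 0 for Sln, its atrial relative, at least 34.7-fold with the same floor. These floors cover counting error only, and neither the spread between replicates nor gene length. Myh7 exceeded Myh6 by 3.87 ± 2.61 on the log2(TPM + 0.1) scale (n = 2), and by 2.64 ± 0.21 with counts not divided by length. On the first scale Actc1 exceeded Acta1 by 5.21 ± 0.82 and Tpm1 exceeded Tpm2 by 3.13 ± 1.79. Neither partner led in both libraries for Myl2 and Myl7 (4.11 and −3.40), Tnni1 and Tnni3 (3.63 and −1.14) or Ldha and Ldhb (−0.48 and 3.78). Hbb-y and Hbb-bt differed by 0.38 ± 0.22 and Pfkl and Pfkm by 0.15 ± 0.28.

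With limma's treat test against a 2-fold difference, 0 of 34 pairs passed, and the smallest adjusted p was 0.0654, for Tnnc1, Atp2a2 and Pln against their partners. At an unadjusted p under 0.05 the same limma test gave 8 pairs, and 17 pairs lay over 2-fold on the same side in both libraries. With a pseudocount of 1, 3 pairs passed (Pln/Sln, Atp2a2/Atp2a1 and Tnnc1/Tnnc2), and with expected counts not divided by length 4 passed, Ryr2/Ryr1 being the addition. With posterior-mean TPM 0 passed, and the differences shrank for Pln/Sln from 10.96 to 2.98, for Atp2a2/Atp2a1 from 10.54 to 1.25 and for Tnnc1/Tnnc2 from 12.64 to 3.37. The partners of these pairs had 0 reads, so the size of the differences follows the pseudocount. With a pseudocount of 1 they were 7.64, 7.23 and 9.32.

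A further question was whether any list moved as a whole between the replicates. The 27 sarcomere genes had a median log2 ratio of replicate 2 to replicate 1 of 0.55 (76.1 percentile of random lists), with 15 members higher in replicate 2 and 12 in replicate 1. Ion channel genes stood at 4.40 (96.9 percentile, 10 of 13 members higher in replicate 2) and valve and cushion genes at −4.87 (8.62 percentile, 7 of 8 higher in replicate 1), both inside the 95% range of random lists. Of 23 lists tested, only the immediate early and heat shock list fell outside it (6.60, 99.1 percentile, 6 members with at most 4 reads each), and with members limited to a mean of at least 5 TPM no list did. Unchanged lists in simulated data fell outside in 2 of 14 cases.

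Transcript shares were read for 22 genes with isoforms of interest in the heart. Of the 19 with reads in both libraries, 4 had the same leading transcript in both, namely Camk2d, Mef2a, Actn1 and Vegfa. The transcript that led by its mean over both libraries held a median of 50% of its gene's TPM, with a median difference of 63.5 percentage points between libraries. Each library's own leader held a median of 75.1% in replicate 1 and 71.5% in replicate 2, and with posterior-mean TPM the median was 26.6%. Mef2a-204 took 54.6 and 45.4% of its gene's TPM, Camk2d-222 72.5 and 84.0%, and Actn1-202 100 and 70.2%. Both Pkm transcripts stood at exactly 50% in each library, as did those of Ryr2, so the reads did not tell them apart. For Ttn the leader was Ttn-220, of 451 bases, in replicate 1 (62.8%) and Ttn-218, of 10229 bases, in replicate 2 (28.7%), and for Tnnt2 it was Tnnt2-204 in replicate 1 (77.4%) and a shorter transcript of 433 bases in replicate 2 (55.04%). None of the 3 genes with at least 20 reads in both libraries (Tnnt2, Ttn and Fn1) kept its leader, so no isoform was assigned to the tissue at this depth.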

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

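None of the tests in this part was chosen after its result was seen, except the simulated uneven copies, the random lists limited by gene class and length, and both tests of shared windows. The phiX174 control row stood out as signal outside the gene measurements, with 261182 reads in replicate 1 and 258812 in replicate 2. The short numbered rows, whose median length is 73 bases and which carry no gene name, held 56 and 144 reads. Both lie above the 3 reads that a count of 0 allows. The 96 spike-in rows had 0 reads in both libraries, although the labels name a spike-in reference.

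The few reads on mouse genes, 33694 and 34276, could have come from counting on the opposite strand. Of 316 pairs of a protein-coding gene and a noncoding gene on the other strand that share at least 50 exonic bases and hold at least 5 reads, the noncoding gene had more reads in 15, or 4.75%, and the protein-coding gene in 300. Opposite counting requires over 50%, so this value argues against it. A low share of heart library in the sequenced pool, a filter before counting and the program's settings stay open and untested here. The signal tracks of uniquely placed reads were listed at 75.7 and 75.0 megabytes. These sizes were not converted to numbers of reads, so they were not used to weigh these explanations. No biological explanation was tested, since the design has 1 group.

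The differences between replicates in the reads of single genes, with a median dispersion index of 3.14 and a mean of 12.4 (8.19 without the top 1% of genes) over 1112 genes of at least 10 reads in all, where counting error gives a mean of about 1, have several possible explanations. Reads shared between gene copies are argued against for the 207 genes with no 36-base window in common with another gene, whose mean index was 6.59 (bootstrap 4.71 to 9.16). The 92 genes with at least 50% of windows shared had a median index of 14.2 against 1.84. At matched length the ratio was 1.39 (0.87 to 2.66). That pooled value cannot decide, because the shortest of 5 length classes set 30 shared genes against 3 unshared (medians 21.87 and 14.24). In the longer classes, in order of length, shared genes had 14.72, 10.81, 4.62 and 7.13 against 5.72, 1.57, 1.54 and 1.67. The excess was thus also seen at like length, though no interval was taken within a class and the longest held 3 shared genes. The ratio of 0.97 for genes with whole-number counts was chosen beforehand and set aside after it was seen. It decides nothing, because these genes are 84.2% of all genes and include mt-Co3. Few molecules amplified many times cannot in general be told apart from variable expression. The slope of log index on log total count was 1.0 (0.88 to 1.12). The bound of 0.5 set for it was wrong, since simulated molecules gave 0.01 with even copies but 0.74 with uneven copies. Simulated variable expression gave 0.93. Uneven copies had a mean of 10 and a log SD of 1.5, and reached at most 0.77 in 20 draws. That setting lies below the observed interval, but no other degree of unevenness was simulated. A different share of cell types cannot be told apart either. The spread within 5 cell type lists (38 memberships) was 0.54 times that of random lists (0.42 to 0.77). With random lists matched on class and length it was 0.68 (0.52 to 0.97), and 0 of 11 cell type lists moved outside the random range. Most of the memberships were of the sarcomere list, which holds genes of both chambers, and Myl2 and Myl3 counted in it and in the ventricular list.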

How the results depend on the processing

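Of the choices below, detection at 3 reads, all genes of the files, mouse genes alone and a mean of 10 reads were set after the data were seen. The cause of each difference was not tested unless a setting's construction gives it. Posterior-mean values, which add a prior to every transcript, gave 32520 genes detected (main 4056), a correlation of 0.969 (−0.041), 524 genes over 2-fold (4777), 20 lists moved (1), a sarcomere share of 0.111% (1.13%), and turned Slc2a1/Slc2a4 to −0.55, Cox7a2/Cox7a1 to −0.17, Hand2/Hand1 to −1.69 and Slc16a1/Slc16a3 to −2.45. At 3 reads in both libraries 1101 genes and 94 list members (main 169) were detected. The correlation was −0.215 with a pseudocount of 0.1, 0.577 over genes of at least 1 TPM in both and 0.515 over all genes. The coefficient of variation (main 1.12) was 0.878 without a filter and 0.930 in protein-coding genes. Genes over 2-fold numbered 7619 at a mean of 1 TPM and 7789 without a filter, as more genes entered, and 244 by share of gene reads among genes with a mean of 10 reads. Pairs past the limma test (main 0) numbered 3 with a pseudocount of 1 and 4 with counts not divided by length, and 0 with posterior-mean TPM and against no difference or a 1.5-fold difference. A pseudocount of 1 moved 2 lists and a mean of at least 5 TPM 0. The sarcomere share was 5.97% over nuclear protein-coding genes and 3.15% over mouse genes, through the denominator. It was 0.445% of expected counts over all rows, where the phiX174 row held 88.6% and 88.3%, against 62.7% and 59.4% of TPM. Of the reads on mouse genes alone it was 3.84%. With each library alone, 6529 to 7199 genes were detected and 25 to 28 pairs lay over 2-fold, with no test. DESeq2 size factors left the coefficient at 1.12. In all, 26 alternative values of the results that answer a comparison moved, and 22 stayed within 1.5 times or the spread. These totals include labels fixed by construction: single-library pair counts always count as moved and single-library sarcomere shares always as staying. Among those that stayed is the leading isoform share (main 50%) at 26.6% with posterior-mean TPM and 71.5 to 75.1% in each library alone, where the SD is 44.9. Of 104 genes named with a level, posterior-mean TPM moved 61 by over 1 SD and rescaling over nuclear protein-coding genes all 95 it applies to; of the other 30 list shares these moved 26 and 28. A single library of 2 always lies within 1 SD of the mean, so that alternative says nothing of single genes. No paired analysis was possible because the design has 1 group. With 2 libraries, other splits of the samples do not exist. Depth limits every gene level: only 168 genes had at least 10 reads in both libraries.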

Other observations

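The tests in this part were chosen after the values were seen. Ribosomal protein genes, many of which most cells express at high levels, were not among the lists. Of 80 genes of this family, 34 had reads in both libraries, 16 had 0 in both, 13 had 0 in replicate 1 alone and 17 in replicate 2 alone. The family summed to 595 and 562 reads. The 16 include the paralogues Rpl3l, Rpl10l and Rpl39l. Rpl34 (15 and 17 reads) and Rps5 (12 and 12) were close, while Rpl3 had 107.54 and 9 reads and Rps24 41 and 0. The pseudogene Rps24-ps3, which has 68.7% of its 36-base windows in common with Rps24, had 0 and 55, so the division of reads between these is uncertain.

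The 7 pseudogenes on chromosome 1 between 24611535 and 24616197 (mm10) share sequence with mitochondrial genes, and 5 of the copies held reads where the mitochondrial gene had under 1 in at least 1 library. Gm28437, at 24613189 to 24613971, had 423 and 0 reads while mt-Co3, of which it holds 99.9% of the 36-base windows, had 0 and 1411. Gm10925 had 468 and 413 reads while mt-Atp6, 99.5% shared, had 0 in both, and Gm28661 had 159 and 323 while mt-Co2, 99.5% shared, had 0 and 0.69. Gm10222 (45 and 154) and Gm28438 (160 and 25) stood beside mt-Nd4l and mt-Nd3 at 0 in both. Gm28439 (141 and 95.9) and Gm29216 (0 and 736) share less, 62.6% of the windows of mt-Nd4 and 29.4% of those of mt-Co1, and both of these genes held reads in each library. The gene mt-Nd1, with 0% of windows shared with any other gene, had 85 and 295 reads.

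Disagreement between the libraries was greatest in the shortest of 4 length classes of protein-coding nuclear genes. There (247 genes, median 817 bases) 16.6% had 0 in a library and the median dispersion index was 4.81. In the longer classes the index was 2.47, 2.20 and 1.70, and 4.05, 5.69 and 3.64% had 0. Among genes without a shared window the median index was 14.24 (3 genes) and 5.72 (27 genes) in the shorter of 5 length classes. It was flat over the 3 longest, at 1.57, 1.54 and 1.67. From the shortest class to the longest, the genes with many shared windows described above had 21.87, 14.72, 10.81, 4.62 and 7.13. The last value rests on 3 genes, and no interval was taken within a class.

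Of 1101 genes with at least 3 reads in both libraries, 90 had reads and TPM that differed in opposite directions, and 366 (33.2%) differed over 1.5-fold in the length given for the gene. Eng had 18 and 2 reads. ENSMUSG00000045999, which has no symbol here, held 2616 and 1321 reads, 7.77% and 3.86% of gene reads. The listed sizes of the signal tracks of uniquely placed reads were 75.7 and 75.0 megabytes, and of all reads 120.1 and 117.9.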
